A study of Homo sapiens with 9 samples.

How the data were processed

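MicroRNA was profiled in 9 tumours grown under the skin of mice from TFK-1, an established human cell line derived from a cholangiocarcinoma, a cancer of the bile duct. Per the labels, 5 tumours were controls and 4 came from the group given galectin-9, a galactose-binding lectin. The injections were given under the skin 3 times a week for 7 weeks, at 30 or 90 μg per animal per day, per the labels' protocols. No label states which of the 2 doses a given tumour received. The descriptions of all 4 galectin-9 tumours begin with 30, the number of the lower dose, but the labels do not say what it stands for, so the 4 galectin-9 tumours were treated as 1 group. The labels number the tumours within each group and do not say that each came from its own mouse, so p-values measure only the spread between these samples, which may in part be technical.

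Total RNA was labelled with the dye Hy3 and hybridised to a custom array with locked nucleic acid capture probes, 1 colour and 1 array per tumour, per the labels' protocols. Each scanner file gave 3200 spots, among them 2019 human miRNA probes with 1 spot each, 925 blank spots, 24 negative control spots, 16 spike-in spots and 22 custom spots whose content the files do not state. The deposited scanner values are intensities, the median and mean brightness of a spot's pixels and of its local background, not background-corrected and not normalized, per the file headers. The scanner and its settings are not given in the sources used here. The files carry no slide number or scan date, so arrays could not be grouped by either, and no spot had a quality mark. No values were identical between arrays beyond single spots: the most that any pair of arrays shared was 56 of the 2019 signals.

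From these intensities, the spot median was corrected for local background with normexp (saddle-point method, offset 50, fitted over all spots), log2-transformed and quantile-normalized over the miRNA probes, with control spots left out. This used limma 3.58.1 in R 4.3.3. A probe counted as detected where its uncorrected signal lay above the mean + 2 SD of the blank and negative control spots of the same array, and probes detected on at least 4 of the 9 arrays were tested (968 of 2019). The detection limit ran from 216 to 230 intensity units, against a median probe signal of 216 to 227, so a large share of the probes lay at background on every array. The negative control spots were brighter than the far more numerous blank spots, with array means of 210 to 219 against 193 to 202. With the negative control spots alone as the background, 449 probes passed the filter in place of 968. A detected probe near the limit has a compressed fold change, because of the offset. The number of arrays limits the precision.

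Galectin-9 tumours were compared with control tumours by limma (lmFit and eBayes), with group as the only term and all 9 tumours in the fit. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Differences are galectin-9 minus control on the log2 scale of normalized intensity, and mean ± SD is over the tumours of a group. Where a probe was at background on every array of a group, the fold allows for the detection limit but not for the spread between tumours. It is the mean of the group with signal over the mean of the other group. There, each array counts with the higher of the probe's own value and the lowest signal among detected probes. A probe at the scanner limit of 65535 has no fold. In simulated data with the real means and spreads of the 968 probes, independent between probes, 200 of which were changed, the fit recovered 70.7% of probes changed by 1.5-fold, 92.9% of those changed by 2-fold and 99.3% of those changed by 4-fold. The adjustment is stricter where fewer probes change, which was not simulated. The shares therefore do not tell how well a change in only a few probes would be found.

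Before the data were examined, 19 miRNA lists were fixed: markers of epithelium, red blood cells, white blood cells, stroma and vessels, and muscle; the let-7, miR-15/16, miR-29 and miR-30 families; the miR-17 cluster with its paralogues and the miR-183 cluster; the chromosome 19 and DLK1-DIO3 clusters; miRNAs linked to p53; miRNAs reported higher or lower in cholangiocarcinoma; the hypoxia-induced miR-210; miR-22, reported to target the galectin-9 transcript; and every miR with a number of 1000 or higher, as a description of the array. The 17 lists with at least 3 tested members were tested with limma's camera, which sets a list against the other probes (preset correlation 0.01, and again with the correlation estimated from the data), and with fry, which asks whether a list's members move one way on balance. Adjustment was over the 17 lists. List means per tumour were compared with an exact two-sided permutation test over the 126 splits of the 9 tumours, whose smallest p is 0.00794. Detection was compared per probe with Fisher's exact test.

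The named miRNAs follow a rule fixed at the same time. It takes up to 12 probes with the largest rise and up to 12 with the largest fall among those with adjusted p under 0.05, and where a direction has fewer, it fills up to 12 with the smallest unadjusted p as values that did not pass. It adds the members of each list past the threshold or, with none, the 2 with the smallest p, every tested arm of miR-22, and the 10 brightest probes. Other miRNAs named in the text were chosen after their values were seen. miRNA names are those of the array's files. No genome build is stated in the files, so no coordinates are given. Probes for human miRNAs can also bind mouse miRNAs of the same or nearly the same sequence, and the arrays do not separate tumour cells from mouse host tissue.

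A value table deposited by the authors holds normalized intensities on a linear scale for 591 of the 2019 probes and is empty for the other 1428. Its processing, including the background correction and the reason for the empty probes, is not given in the sources used here. Every column holds the same sorted values, with a median of 121, which is what quantile normalization leaves, and its values are neither centred per probe nor ratios. Its rows were matched to the arrays by probe identifier. Within each column, Spearman's rho across the 591 probes with the scanner signal of the array of the same label was 0.779 to 0.844, and all 9 columns correlated best with the array of galectin-9 tumour 4, while the background corrections used here left rho at 0.965 or above. By deviations from each probe's mean, 3 of the 9 columns correlated best with their own array, with r of 0.387 at most. The table was therefore used only as an alternative, with an offset of 50 before log2.

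The alternatives set before the data were examined were 6 other normalizations (scaling to the median or 75th percentile of the probes detected on all arrays, scaling to the 75th percentile of all probes, cyclic loess, none, and quantile normalization of the probes detected on all arrays), 3 other background treatments (subtraction with a floor, none, and normexp with an offset of 16), the deposited value table, 3 other filters, limma with a trend and robust fit, with array weights and with treat at 1.5-fold, an exact rank-sum test, the tumour number as a block, an estimated correlation in camera, detection limits at 1 and 3 SD, and leaving out each tumour in turn. Added after seeing the data were the spot mean in place of the median, the negative control spots alone as the background for detection, scaling to the spike-in spots, the ratio of both spike-in controls as a covariate, and a fit without control tumour 2 and galectin-9 tumour 4. A slide or scan block was not run.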

Results

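miRNA intensities were measured on 9 arrays, 1 for each of 5 control and 4 galectin-9 tumours of the cholangiocarcinoma line TFK-1 grown in mice. The study asked which miRNAs accompany the treatment of such tumours with galectin-9. Of the 2019 human miRNA probes, 785 to 1021 were detected on a control array and 828 to 1005 on a galectin-9 array. The means were 950.0 ± 96.5 (SD, n = 5) and 906 ± 86.0 (SD, n = 4), a difference within the spread between tumours (exact two-sided permutation p = 0.452). All 9 arrays detected 356 probes, and no array detected 150. The first spike-in control gave a mean signal of 9812 on the array of control tumour 2 and 14353 to 26961 on the other arrays. The ratio of the second spike-in control to the first ran from 0.482 in control tumour 5 to 0.797 in control tumour 4.

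The 10 probes with the highest mean normalized signal over the 9 tumours were those for miR-4454, miR-5100, miR-23a-3p, miR-21-5p, miR-1260b, miR-23b-3p, let-7a-5p, miR-31-5p, miR-4286 and let-7c. miR-21-5p, a miRNA abundant in many carcinomas, stood at 13.91 ± 0.69 (log2, SD, n = 5) in control and 13.97 ± 0.57 (n = 4) in galectin-9 tumours. miR-31-5p stood at 13.30 ± 0.61 and 13.03 ± 1.17, and let-7a-5p, of the let-7 family of growth-restraining miRNAs, at 13.32 ± 0.26 and 13.25 ± 0.15. miR-23a-3p was at 14.15 ± 0.39 and 13.96 ± 0.27, and miR-23b-3p at 13.56 ± 0.32 and 13.42 ± 0.20. miR-4454 reached the scanner limit on 7 of the 9 arrays, so no fold is given for it. The other 9 differed between the groups by −0.27 to 0.26 on the log2 scale, with unadjusted p of 0.117 or more. In the deposited value table only 6 of these 10 were among the 10 brightest.

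No miRNA differed between galectin-9 and control tumours after adjustment. Of the 968 probes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.997. At an unadjusted p under 0.05 there were 30 probes, 22 higher and 8 lower in galectin-9 tumours, where 48.4 would be expected with no difference. The directions depended on the settings: 29 were higher and 0 lower with no normalization, but 8 higher and 18 lower in the deposited value table, 13 and 19 without control tumour 5, and 26 and 29 without galectin-9 tumour 3. The exact rank-sum test gave 19 at unadjusted p under 0.05 and 0 after adjustment. No difference exceeded 1 on the log2 scale. The 95% confidence interval lay within a 2-fold change in either direction for 920 of the 968 probes and for 311 of the 356 probes detected on every array (87.4%). Both counts refer to normalized intensity. The offset compresses differences near the detection limit, so for dim probes these intervals do not exclude a 2-fold change in amount. The groups did not overlap for 10 probes (1.03%), and chance gives 1.59%.

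**Figure D1:**
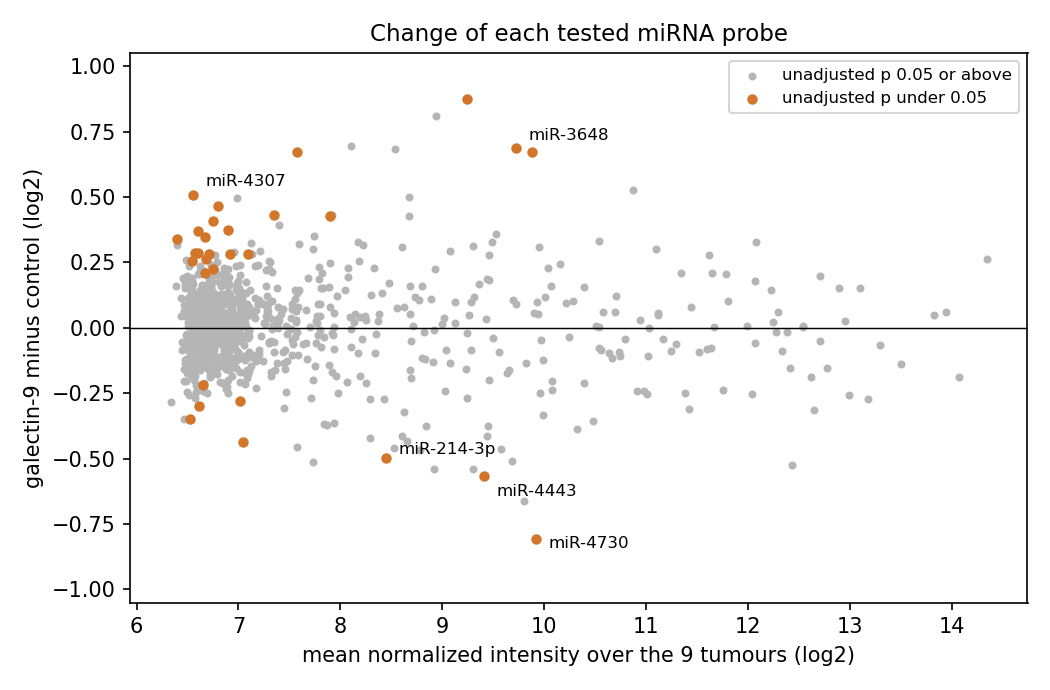
Each point is 1 of the tested miRNA probes, without miR-4454, with its mean normalized intensity over the 9 tumours (log2) on the horizontal axis and the difference galectin-9 minus control (log2) on the vertical axis. The coloured points are the 30 probes at unadjusted p under 0.05, none of which passed adjustment, and all points lie between −0.81 (miR-4730) and 0.87 (miR-6126).

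The miRNAs with the smallest p on the higher side were mostly dim. The first of them, miR-4307, stood at 6.32 ± 0.21 (SD, n = 5) in control and 6.83 ± 0.20 (SD, n = 4) in galectin-9 tumours. The difference was 0.51 ± 0.14 (SE), with an adjusted p of 0.997 by limma. It was above the detection limit on 1 of 5 control and 4 of 4 galectin-9 arrays, and so were miR-2113 (0.41 ± 0.12), miR-4756-5p (0.46 ± 0.13), miR-4430 (0.37 ± 0.12) and miR-1237-3p (0.26 ± 0.10). Also not detected on every array were miR-548z and miR-548h-3p, which share a probe (0.35 ± 0.11), miR-4750-3p (0.29 ± 0.10), miR-106a-3p (0.23 ± 0.09) and miR-143-5p (0.28 ± 0.11). Detected on every array were miR-101-3p (0.28 ± 0.11), miR-1275 (0.43 ± 0.17) and miR-3648, which stood at 9.41 ± 0.14 in control and 10.10 ± 0.72 in galectin-9 tumours (0.69 ± 0.28, 1.61-fold). Without galectin-9 tumour 4 the difference was 0.36 for miR-3648 and 0.28 for miR-1275. All 12 had the adjusted p of 0.997.

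On the lower side, miR-4443 and miR-4730 were the brightest. miR-4443 stood at 9.66 ± 0.40 in control and 9.09 ± 0.31 in galectin-9 tumours (−0.56 ± 0.21), and miR-4730 at 10.28 ± 0.65 and 9.47 ± 0.48 (−0.81 ± 0.33). miR-214-3p, a miRNA of fibroblasts and other stromal cells, was at 8.67 ± 0.36 and 8.17 ± 0.38 (−0.50 ± 0.22), and miR-718 at 7.78 ± 0.30 and 7.32 ± 0.41 (−0.46 ± 0.21). miR-3928 (−0.44 ± 0.17), miR-193b-5p (−0.22 ± 0.09), miR-204-5p (−0.28 ± 0.12), miR-877-5p (−0.30 ± 0.13), miR-550b-3p (−0.25 ± 0.11), miR-4710 (−0.25 ± 0.12) and miR-556-5p (−0.25 ± 0.12) were dimmer. miR-5582-3p was detected on all 5 control arrays and on none of the 4 galectin-9 arrays. With the detection limit allowed for, its mean was 1.16-fold higher in control tumours (limma adjusted p = 0.997). This fold is no lower bound, because it leaves out the spread between tumours. The confidence interval of the log2 difference ran from −0.67 to −0.03. The groups also overlapped, with 6.54 in galectin-9 tumour 4 and 6.47 in control tumour 4. None of these 12 passed adjustment either.

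Detection itself differed little. miR-5582-3p was the only probe detected on every array of one group and on none of the other, and no probe had the opposite pattern. Fisher's exact test gave p under 0.05 for 25 probes, with a smallest p of 0.00794, and 0 after adjustment. With 9 arrays, a single probe cannot reach an adjusted p under 0.05. With the limit at 3 SD in place of 2 SD, or with the negative control spots alone, no such probe remained. Leaving out 1 tumour at a time gave between 1 and 9 such probes, most without galectin-9 tumour 3.

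The miRNA miR-22, which is reported to target the galectin-9 transcript, was examined arm by arm. Its major arm, miR-22-3p, stood at 12.15 ± 0.20 (n = 5) in control and 11.89 ± 0.34 (n = 4) in galectin-9 tumours. The difference was −0.25 ± 0.17 (SE), with a limma adjusted p of 0.997. Galectin-9 tumour 3 stood at 12.39, apart from the other galectin-9 tumours at 11.65 to 11.80. The other arm, miR-22-5p, differed by −0.10 ± 0.12 (limma adjusted p = 0.997). Both arms were detected on all 9 arrays.

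The fixed lists asked whether cell types or miRNA families moved together. White blood cell markers were lower in galectin-9 tumours in all 9 tested members, with a median difference of −0.24. miR-155-5p, which rises in activated lymphocytes and macrophages, stood at 9.01 ± 0.31 (n = 5) in control and 8.63 ± 0.65 (n = 4) in galectin-9 tumours. The lymphocyte miRNA miR-150-3p was at 6.94 ± 0.09 and 6.78 ± 0.03. It was detected in 4 of 5 control and none of 4 galectin-9 tumours, where its mean was 1.11-fold lower. The confidence interval of its log2 difference, −0.34 to 0.04, included no difference. miR-223-3p, of neutrophils and monocytes, was at 11.09 ± 0.14 and 10.84 ± 0.47. No member passed on its own, also when adjusted over the list alone. The list was called by camera with the preset correlation (adjusted p = 0.0235), but not with an estimated correlation (adjusted p = 0.939), nor by fry (adjusted p = 0.971). The list mean per tumour was 8.56 ± 0.15 in control and 8.33 ± 0.44 in galectin-9 tumours (exact permutation p = 0.278).

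The galectin-9 tumours did not move alike in this list. Its median deviation was −0.63 in galectin-9 tumour 4, −0.31 in tumour 1 and −0.06 in tumour 2, but 0.55 in tumour 3, the highest of all 9 tumours. Control tumours ranged from −0.11 to 0.26. Without galectin-9 tumour 4 the list was not called (camera adjusted p = 0.419), and the call was also lost on leaving out any of 6 other tumours singly. Without galectin-9 tumour 3 the camera adjusted p was 6.29e-06. Tumour 4 was also the array least correlated with the others (median r 0.930 across the 356 probes detected on every array, against 0.948 to 0.967).

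**Figure D2:**
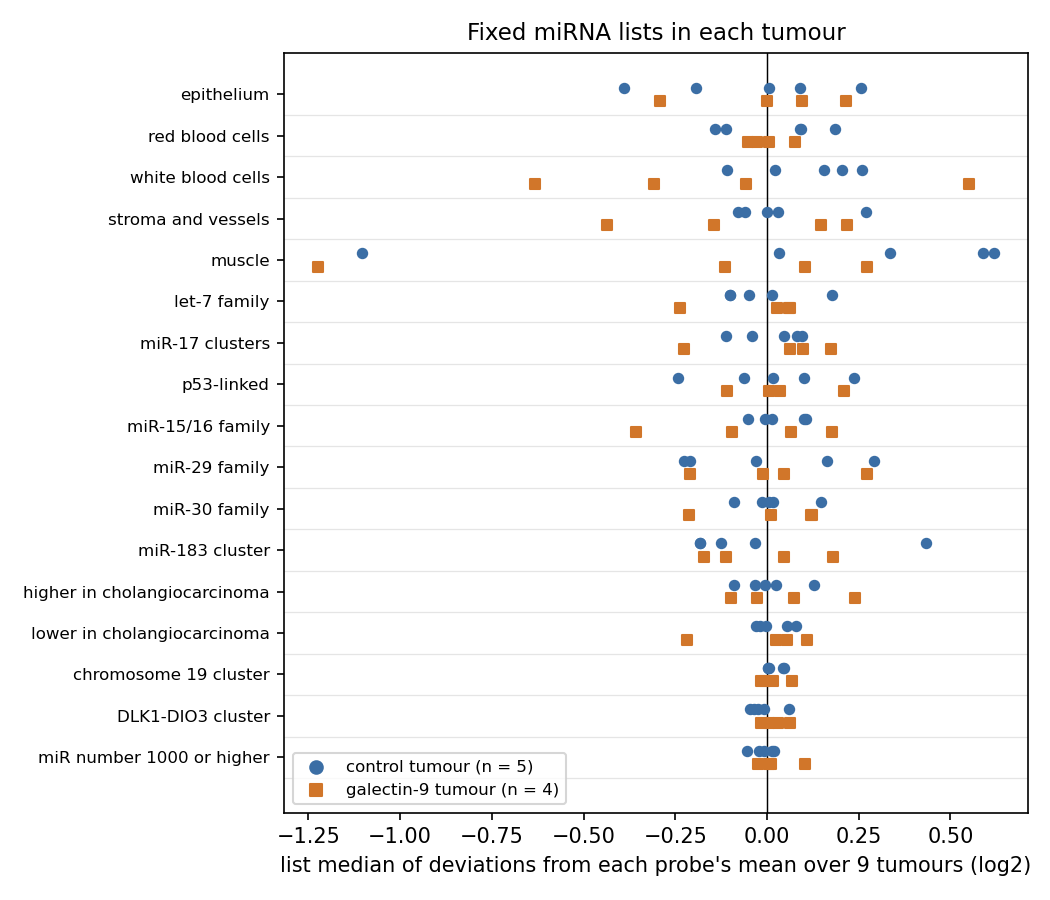
Each point is 1 tumour, and its horizontal position is the median, over a list's tested miRNAs, of the deviation from each probe's mean over the 9 tumours (log2). Circles are the 5 control and squares the 4 galectin-9 tumours. White blood cell miRNAs range from −0.63 to 0.55 within the galectin-9 group, and muscle miRNAs lie lowest in control tumour 5 (−1.10) and galectin-9 tumour 4 (−1.22).

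Muscle miRNAs had the largest median difference of any list, −0.42 over 5 tested members, of which 4 were lower and 1 higher. miR-133b stood at 10.09 ± 1.00 (n = 5) in control and 9.43 ± 0.95 (n = 4) in galectin-9 tumours, and miR-206, of skeletal muscle, at 8.47 ± 0.42 and 8.05 ± 0.68. The list was not called (camera adjusted p = 0.406, and 0.994 with an estimated correlation). Camera with the preset correlation did call it under 4 alternatives, one of them leaving out control tumour 5 (adjusted p = 0.00824). Without galectin-9 tumour 4 its median relative to all tested probes was −0.10 in place of −0.43 (camera adjusted p = 0.918), so most of the difference rested on that tumour. Markers of stroma and vessels were lower in 11 of 13 tested members, with a median of −0.05 (camera adjusted p = 0.540). The 2 members with the smallest p went opposite ways, miR-143-5p higher (0.28 ± 0.11) and miR-214-3p lower (−0.50 ± 0.22). The list also included the endothelial miR-126-3p, at 12.28 ± 0.13 and 12.27 ± 0.29. Red blood cell markers did not separate the groups: miR-451a, the main miRNA of red cells, was at 10.63 ± 0.65 and 11.16 ± 0.24, and miR-486-5p at 7.16 ± 0.16 and 7.05 ± 0.10. Of their 4 tested members 1 was higher, so that the median was −0.05 and the mean 0.08 (camera adjusted p = 0.987).

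Epithelial miRNAs, which the tumour cells and mouse skin can both carry, did not differ on balance, with 9 of 16 tested members higher, 7 lower and a median of 0.01. miR-141-3p stood at 11.49 ± 0.29 (n = 5) in control and 11.77 ± 0.53 (n = 4) in galectin-9 tumours, and miR-203a at 12.66 ± 0.39 and 12.14 ± 0.97. Camera placed the list slightly below the other probes although its median and mean were above 0 (camera adjusted p = 0.987). The same difference in sign held for the miR-17 clusters, with a median of 0.00 and a mean of 0.01 over 22 members (camera adjusted p = 0.987). Among miRNAs reported higher in cholangiocarcinoma, 8 of 16 were higher and 8 lower, with a median of 0.02 and a mean of −0.03 (camera adjusted p = 0.987). Among those reported lower, 12 of 17 were higher, with a median of 0.06 (camera adjusted p = 0.987). The members of that list with the smallest p, miR-204-5p (−0.28 ± 0.12) and miR-214-3p (−0.50 ± 0.22), were both lower.

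The remaining families and clusters showed no shift by camera. The let-7 family had a median of −0.04 with 7 of 17 members higher, the miR-15/16 family −0.09 with 2 of 11 higher, the miR-29 family 0.06 with 5 of 7 higher and the miR-30 family −0.01 with 5 of 10 higher. The miR-183 cluster had a median of 0.02 over 4 members and the p53-linked miRNAs 0.03 over 12 members, among them miR-1246 at 8.57 ± 0.85 (n = 5) and 9.38 ± 0.85 (n = 4). The chromosome 19 cluster was dim in both groups and had a median of −0.04 over 22 members, and the DLK1-DIO3 cluster 0.04 over 41 members, among them miR-494 (0.31 ± 0.15) and miR-376a-3p (0.23 ± 0.11). The camera adjusted p of these lists ran from 0.444 to 0.987. miR-210, which hypoxia induces, stood at 10.26 ± 0.36 and 10.22 ± 0.26 (−0.03 ± 0.19). No member of any list passed the limma adjustment, over all probes or adjusted over the list alone.

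miRNAs with a number of 1000 or higher were the other list that camera called with the preset correlation. Of 448 tested members, 261 were higher and 187 lower in galectin-9 tumours, with a median difference of 0.03 (adjusted p = 0.0431, and 0.939 with an estimated correlation). The list mean was 7.26 ± 0.03 (n = 5) in control and 7.30 ± 0.09 (n = 4) in galectin-9 tumours (exact permutation p = 0.405). Without galectin-9 tumour 4, relative to all tested probes, the median was −0.01 in place of 0.02. Fry called 0 of the 17 lists, and camera with an estimated correlation also called 0.

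Some of the widest differences did not follow the groups. The miRNAs miR-192-5p and miR-194-5p, processed from shared transcripts and abundant in gut, liver and kidney epithelium, had the largest within-group SDs of all tested probes (2.05 and 1.46). These 2 and the others of this paragraph were chosen after their values were seen. miR-192-5p ranged from 7.69 in control tumour 4 to 12.98 in galectin-9 tumour 1, a 39.0-fold span over the 9 tumours, with 8.45 in control tumour 2, 8.44 in galectin-9 tumour 2 and 10.13 in galectin-9 tumour 3. The other 4 tumours lay between 11.36 and 12.02. Within the groups it ran from 7.69 to 12.02 in control and from 8.44 to 12.98 in galectin-9 tumours. The group means were 10.39 ± 2.14 (n = 5) and 10.73 ± 1.92 (n = 4), with limma adjusted p = 0.997. miR-215, of the same seed family as miR-192, and miR-338-3p were also lowest in control tumours 2 and 4 and galectin-9 tumour 2, with spans of 2.70-fold and 5.30-fold. The muscle miRNA miR-133b spanned 6.08-fold over the 9 tumours, from 8.27 in galectin-9 tumour 4 and 8.40 in control tumour 5 to 10.87 in control tumour 1. The epithelial miR-200c-3p spanned 2.92-fold, less than miR-192-5p, miR-338-3p and miR-133b but more than miR-215. Its within-group SD of 0.60 was near that of miR-215 (0.62), so it was not a stable reference. By this SD, miR-200c-3p ranked 37 and miR-215 ranked 35 among the tested probes. In control tumours 2 and 4 and galectin-9 tumour 2, miR-215 stood at 6.66 to 6.75, near the detection limit. There the offset compresses its span and SD, which does not hold for miR-200c-3p.

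**Figure D3:**
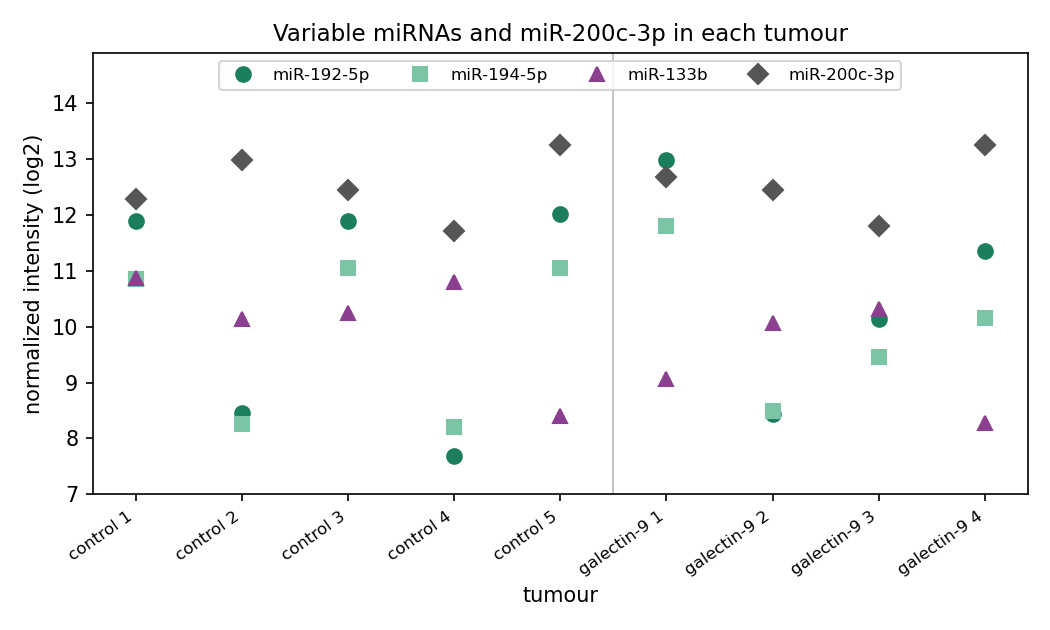
Each marker is the normalized intensity (log2, vertical axis) of 1 miRNA in 1 of the 9 tumours (horizontal axis), with the 5 control tumours left of the line and the 4 galectin-9 tumours right of it. miR-192-5p runs from 7.69 to 12.98, with tumours of both groups at the low and the high end, while miR-200c-3p lies between 11.71 and 13.25.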

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

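In each group of 4 or 5 tumours, the gap between the most extreme tumour and its nearest neighbour was set against the group's range, for the named miRNAs, the list medians and the array measures. Of 176 such tests 10 exceeded the 95% critical value, where chance alone gives about 8.80. The values are given without a biological explanation.

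Galectin-9 tumour 4 stood apart in 4 of them. Its miR-451a was 10.80, below 11.27 to 11.29 in the other galectin-9 tumours, and its miR-4756-5p was 7.49, above 6.89 to 6.94. Its miR-5100 was 14.26, while the other 3 tumours were at 14.56, and its let-7 list median was −0.24, against 0.03 to 0.06. Control tumour 2 had the lowest miR-5100 of its group, 13.47 against 14.26 to 14.56, and the highest miR-4307, 6.69 against 6.18 to 6.29. miR-101-3p was 7.13 in control tumour 4 and 6.91 to 6.94 in the other controls. let-7a-5p was 13.47 in galectin-9 tumour 1 and 13.18 in the other 3. Quantile normalization gives each rank on an array the same value, so these equal values, and those of miR-5100, are equal ranks. With 3 equal values, any other value of the remaining galectin-9 tumour exceeds the critical value. The median of the miR-183 cluster list was 0.43 in control tumour 5, against −0.18 to −0.03. The median local background, as log2 of intensity, was 7.25 on the array of galectin-9 tumour 2, against 7.34 to 7.36 on the other galectin-9 arrays.

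The arrays also carry custom spots outside the human miRNA set, whose content the files do not state. Of 22 such spots, 15 lay above the detection limit on all 9 arrays, the brightest with a median signal of 9507. None differed between the groups at an unadjusted p under 0.05 (smallest exact permutation p = 0.0714).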

How the results depend on the processing

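The count of miRNAs past adjustment stayed 0 in all 32 alternatives. At unadjusted p under 0.05 the count of 30 moved to 13 and 12 with scaling to the median and to the 75th percentile of probes detected on all arrays, 1 with spike-in scaling, 75 with no filter, 66 with detection on at least 1 array, 6 with detection on all 9, 4 with quantile normalization of those, 8 with the negative control spots alone, 19 with the rank-sum test, 0 with treat and 19 without control tumour 2 and galectin-9 tumour 4. Leaving out 1 tumour gave 17 to 55: 19 without control tumour 2 or 4, 17 without galectin-9 tumour 1 and 55 without galectin-9 tumour 3. With the tumour number as a replicate block, it was 15. Tumours of the same number deviated with r of 0.42, 0.04, −0.10 and −0.40, so no steady pairing by number was seen. These r were not tested and do not exclude that tumours of the same number shared a slide or a batch. The median of all log2 differences, 0.01, changed sign with the scaling: −0.12 with spike-in scaling, −0.10 with the 75th percentile of probes detected on all arrays, 0.04 with that of all probes and 0.08 with none. Spot mean, spike-in scaling and covariate, negative control spots alone and the fit without both tumours were chosen after seeing the data.

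The count of called lists was 2. It fell to 0 with an estimated correlation, median scaling, 75th percentile scaling over all probes, cyclic loess, no normalization, no background correction, no filter, detection on at least 1 array, and without control tumour 2 and galectin-9 tumour 4. It was 1 with quantile normalization of probes detected on all arrays and with the spot mean, and 4 with the deposited value table. Leaving out 1 tumour gave 0 (without control tumour 1 or galectin-9 tumour 4) to 2. The cause was not tested, and filters change the probes compared.

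Relative to all tested probes' median, the white blood cell list stood at −0.25 and was lower in 28 of 29 alternatives, but called in 11, with adjusted p from 6.29e-06 to 0.939. Its value without a call was −0.25 with an estimated correlation, −0.20 with median scaling, 75th percentile scaling over all probes, no normalization and no filter, −0.19 with cyclic loess and no background correction, −0.27 with quantile normalization of probes detected on all arrays, −0.24 with detection on at least 1 array and −0.16 without control tumour 2 and galectin-9 tumour 4. It reversed to 0.10 in the deposited value table. Most alternatives share the same arrays, and scaling an array by a constant cannot change a value taken relative to all probes. The 28 alternatives are therefore not separate evidence for the direction. Leaving out 1 tumour gave −0.63 (galectin-9 tumour 3) to −0.089 (galectin-9 tumour 4), and −0.17 without galectin-9 tumour 1. The list of miR numbers of 1000 or higher, at 0.02, was called in 12 of 29. Uncalled, it was 0.024 with an estimated correlation, 0.0064 with median, either 75th percentile or spike-in scaling and no normalization, 0.014 with cyclic loess, 0.011 with no background correction, 0.0099 with the replicate block, 0.0027 with no filter, 0.0034 with detection on at least 1 array, and 0.025 with the spot mean. It reversed to −0.0017 without control tumour 2 and galectin-9 tumour 4, and leaving out 1 tumour gave −0.013 (galectin-9 tumour 4) to 0.051. In the deposited value table, besides that list, camera called the miR-17 clusters (−0.36), the miR-30 family (−0.18) and the miRNAs reported higher in cholangiocarcinoma (−0.18, reversed from 0.01). The replicate block changed no other call except muscle (adjusted p = 0.0119), which was called in 4 of 29.

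The count of probes detected in one group alone, 1, was 0 at 3 SD and with the negative control spots alone. Leaving out control tumours 1 to 5 in turn gave 3, 5, 2, 5 and 1, and galectin-9 tumours 1 to 4 gave 3, 2, 9 and 3. The 10 brightest probes kept at least 9, but 6 in the deposited value table. Of 62 named miRNAs with a fold, up to 9 changed sign under another normalization and 17 of 45 in the deposited value table, none past adjustment. A slide or scan block was not run (not in the files).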

Other observations

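Of the tests in this part, those on the value table, on miR-192-5p, on host tissue and on galectin-9 tumour 4 were chosen after their results or closely related values had been seen, as were the correlations.

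miR-31-5p and miR-222-3p, which many carcinoma cells carry at high levels, also varied between tumours of one group. miR-31-5p ran from 11.47 in galectin-9 tumour 1, which had the highest miR-192-5p, to 14.26 in galectin-9 tumour 2, and control tumour 2 stood at 13.99. Across the 9 tumours miR-192-5p and miR-31-5p had a Pearson r of −0.57 (exact permutation p = 0.107, adjusted 0.143 over 4 relations) and a Spearman rho of −0.43 (exact permutation p = 0.243, adjusted 0.324), so no relation was shown. Without the 2 tumours farthest from the median of miR-192-5p, r was −0.63. The muscle list median and the ratio of both spike-in controls had an r of 0.68 (exact permutation p = 0.0419, adjusted 0.0837) and a rho of 0.65 (exact permutation p = 0.0666, adjusted 0.133), which did not pass adjustment either. Without the 2 tumours farthest from the median ratio, r was 0.67. Control tumour 5 and galectin-9 tumour 4, with the lowest muscle medians, had ratios of 0.482 and 0.495, but control tumour 2, at 0.501, had a muscle median of 0.33.

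The 0 miRNAs called between the groups leave nothing for chance to explain. All 100 splits of the 9 tumours that were counted, the real one included, gave as many or more, which any split must, so that share is not a test. Of these splits, 5 gave more than 0 calls, and the highest gave 11. The split with 11 calls, examined because it had the most, parted the tumours by the spike-in ratio (0.482 to 0.592 against 0.682 to 0.797), and so did the split with the most probes at an unadjusted p under 0.05 (0 calls, with ratios of 0.482 to 0.572 against 0.592 to 0.797). The splits with 6 and 3 calls differed from the one with 11 in the side of only 1 and 2 tumours, control tumour 2 among them, while those with 4 and 1 calls differed in 4, the most there can be. A structure of the samples along the ratio is one reading of these calls, but near splits share most of their tumours and so are not separate evidence, a call in 5 of 100 splits is also what an adjusted threshold of 0.05 allows by chance, and the ratio was set against the splits after they were seen, so this is left open. With the ratio as a covariate, 0 miRNAs were called between the groups and 42 had an unadjusted p under 0.05. For the lists, 65 of 100 splits, the real one included, called at least the 2 lists of the real grouping with the preset correlation, and the highest of the others called 8, so chance cannot be excluded.

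White blood cell miRNAs were lower in galectin-9 tumours by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.939) or by fry (adjusted p = 0.971). Chance cannot be excluded, since 12 of 100 splits, the real one included, gave a p as small as the real 0.00138, the smallest of the others being 5.58e-06. Galectin-9 tumour 4 alone may account for the call, since without it the adjusted p was 0.419 and the median relative to all probes was −0.09 in place of −0.25. A lower share of mouse host tissue cannot be told apart, because the difference between the white blood cell and stromal list means, −0.73 ± 0.16 (n = 5) in control and −0.88 ± 0.26 (n = 4) in galectin-9 tumours, was too variable to decide (exact permutation p = 0.341). Galectin-9 tumour 4 had the lowest white blood cell (−0.63), stromal (−0.44) and muscle (−1.22) list medians of all 9 tumours, but also the lowest let-7 median (−0.24). In galectin-9 tumour 2 the white blood cell median was −0.06 and the stromal median 0.22. An effect of galectin-9 on white blood cells in the tumour remains open as well, and the arrays do not separate cell types.

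miR-192-5p and its relatives differed widely between tumours of one group. Noise of single probes is argued against by miR-194-5p, on a separate probe, which varied with miR-192-5p over the 9 tumours (Spearman rho 0.97, exact permutation p = 8.82e-05, adjusted 0.000353, Pearson r 0.99, exact permutation p = 2.20e-05, adjusted 8.82e-05, and 0.99 without the 2 tumours farthest from the median). The median of the 5 members of the miR-200 family spanned 1.30 on the log2 scale, and its widest member, miR-200b-3p, 1.68. This was less than miR-192-5p (5.29), chosen for its spread, and miR-194-5p (3.60), but near miR-215 (1.43). The span of miR-215 is compressed by the offset, because its lowest tumours lay near the detection limit. The family median deviated by 0.10 in control tumour 2 and 0.14 in galectin-9 tumour 2, both low in miR-192-5p, and by −0.58 in control tumour 4. A lower share of tumour epithelium is not excluded, because mouse skin can carry the miR-200 family too. The stromal list median was 0.27 in control tumour 4, 0.22 in galectin-9 tumour 2 and 0.15 in galectin-9 tumour 3, all lower in miR-192-5p. In the tumours high in miR-192-5p it ran from −0.44 to 0.03, but it was 0.00 in control tumour 2, which was low. These values go with a larger host share in most of the low tumours, a relation that was not tested. Poor hybridisation is argued against by the spike-in signal, which spanned 1.62 (Spearman rho with miR-192-5p 0.05, exact permutation p = 0.904 raw and adjusted, Pearson r 0.17, exact permutation p = 0.672 raw and adjusted, and −0.06 without the 2 arrays farthest from the median signal). A difference in the state of the tumour cells is another possible reason for the spread of miR-192-5p and cannot be told apart from the share of epithelium. No group in the labels tests it, since both groups hold low and high tumours.

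The deposited value table did not follow the scanner files of the same labels. The authors' normalization of these arrays is argued against by rank order, since the highest Spearman rho across probes between a column and its own array was 0.844, and by level, since the highest value of the table, 65311, lies above 60832, the mean of the 9 array maxima. An exchange of columns among the 9 arrays is argued against as well, since the highest correlation across probes of any column's deviations with any array's was 0.387. A table computed from a different set of arrays may explain this: 100% of the steps between its sorted values were whole multiples of 1/10 and 5.39% of 1/9, as an average over 10 arrays would give, although rounding to 1 decimal before a constant was subtracted would do the same. The epithelial miRNAs had a median difference, table minus arrays, of −3.55 (log2, 7 probes), against 0.22 over the 344 probes with a table value that all arrays detected. No biological explanation was tested.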
